A study of Mus musculus with 4 samples.

How the data were processed

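The samples were mouse testes from a busulfan model of oligozoospermia. Busulfan is an alkylating drug that kills dividing germ cells and so empties the seminiferous tubules for a time. Per the labels, 2 samples came from the busulfan model alone and 2 from the model treated with Cus-1, a compound from a cuscutae extract, and total RNA was taken from testis tissue. The labels give no dose, no time, no batch and no pairing of samples, and they do not say whether the 2 samples of a group were separate animals. The p-values therefore measure only the spread between these samples, which may be partly technical. Samples were grouped by their source label, and replicates were numbered in the order of submission, so the numbers name samples and pair nothing. The titles of the 2 busulfan samples begin with BPA, which the labels do not explain and which their source label does not contain. Those of the 2 treated samples begin with CUS2, while their source label says Cus-1. What each group received therefore rests on the source label alone, and every fold change with it.

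The authors deposited 1 table with an FPKM value per gene and library, printed to 2 decimals. FPKM is the number of fragments per kilobase of gene and per M (1e+06) mapped fragments. The genome build was mm10, per the submitters' processing notes. The aligner, the counter, the annotation, the strand setting, the gene lengths and any filter are not given in the sources used here. Columns were assigned to samples by the library name that the labels give for each sample. Values of this kind can move when fragments are shared between near-identical copies, when overlapping or antisense genes are counted without strand, and when a few abundant genes take a different share of a library.

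The table held 45536 rows with values and 46 blank rows. A further property of the table is that 910 of its rows carry a dash in place of a gene name, and these held between 0.641% and 0.688% of the summed FPKM of a library. Unnamed rows were left out of all tests. The named rows gave 44509 symbols, of which 115 stood on more than 1 row, and the row with the highest mean was then used. Symbols were matched to the GENCODE M21 annotation of the same build for gene types and positions, and 83.4% of the tested symbols matched. The rest are given without a position.

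Genes at 1 FPKM or more in at least 2 of the 4 libraries were tested, which kept 19837 genes. The test was limma 3.58.1 in R 4.3.3, an empirical Bayes linear model with a mean-variance trend, on log2(FPKM + 1), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. All log2 fold changes are busulfan with Cus-1 minus busulfan on that scale, which understates the change of genes with low values. With 2 libraries against 2, an exact two-sided permutation test of a single gene cannot go below 0.333, so tests rest on the spread pooled across genes. An exact 0 in the table can be a failed estimate, so genes at 0 are described as listed at 0, without a fold.

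Before the data were examined, 26 gene lists were fixed: markers of germ cell stages, of testicular somatic and immune cells, of tissues that can adhere to a testis, and pathways named in the series title or usual for a toxic injury. They hold 580 different genes, 15 of them on more than 1 list. Lists were tested with limma's camera, which compares the genes of a list with all other genes, two-sided, at a preset correlation between genes of 0.01, adjusted over the 26 lists. The same test with an estimated correlation stands beside it. With 4 libraries that correlation is poorly estimated and the test can hardly call any list. Its p rose even where the estimate was below 0, as for polyamine genes (estimate -0.043, unadjusted camera p from 0.0726 to 0.193). A missing call there therefore does not speak against a list, and the preset value may be too low, so the calls stay uncertain. Members were also adjusted over the list alone. The rule for named genes, also fixed then, took up to 10 genes per direction past the threshold, filled up by the smallest p among genes with an absolute log2 fold change of 1 or more, then the genes of the series title, and then the 2 most abundant tested members of each list. Genes named outside this rule are said to be chosen after their values were seen.

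The number of fragments per library was estimated from the low values, because a gene with 1 annotated transcript can only take steps of 1 fragment. FPKM multiplied by transcript length, over transcripts of 300 to 2000 bases, peaked first at 83.0, 77.4, 72.3 and 83.0 in busulfan 1, busulfan 2, Cus-1 1 and Cus-1 2. If that peak is 1 fragment, the libraries held about 12.0, 12.9, 13.8 and 12.0 M fragments. The peak for the next step gave 13.4, 13.8, 14.8 and 12.5 M. Both peaks were sought only within set windows, the next one around a fixed multiple of the first. The estimates could therefore not lie far apart, and the gap between them does not measure their error. At this depth 1 FPKM in a gene of 1 kilobase rests on 12.0 to 13.8 fragments. The lengths the authors used are not given in the sources used here, so these are estimates and no counts were rebuilt from them.

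The model was tested on simulated data with the fitted spread of the 19837 genes. A small part of the genes, all above a minimum mean level, was changed, independently of each other. Past the adjusted threshold came 0% of genes changed 2-fold, 54% of those changed 4-fold, 74% of those changed 8-fold and 90% of those changed 16-fold. Of the unchanged genes, 5.46% passed an unadjusted p of 0.05 and 2 passed the adjusted threshold. A list shifted in the simulation was called and 0 other lists were. In a second run with a smaller spread than fitted, 66% of genes changed 2-fold and 86% of those changed 4-fold passed, and 7 unchanged genes did. The simulation held no correlation between genes and no changed genes at low values. In the data many more genes had a small p, which moves the adjusted cut, so these shares do not carry over directly.

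Other choices, fixed beforehand, changed the pseudocount to 0.1, the low-value filter (none, or 5 FPKM), the scaling (a common total for every library, median-of-ratios, quantile normalization, a total without mitochondrially encoded genes and the 100 most abundant genes, and centring on the Sertoli cell list), the empirical Bayes model (no trend, or robust), the threshold, the correlation in the list test, and the set of libraries (each left out in turn, the lone sample of a group being assumed to vary like the other group). An alternative restricted to genes annotated as protein coding was added after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.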

Results

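RNA from mouse testis was sequenced in 4 libraries, 2 from mice with busulfan-induced oligozoospermia and 2 from such mice treated with Cus-1. The design names the comparison of these 2 groups, and the series title places it in the question of whether Cus-1 restores spermatogenesis through aquaporins, p38 MAPK, SAT1 and GPX4 with less ferroptosis, an iron-dependent form of cell death. The summed FPKM was 726041 and 742689 in busulfan 1 and 2 and 727125 and 739160 in Cus-1 1 and 2, and the low values put the depth at an estimated 12.0 to 13.8 M (1e+06) fragments. Across genes, the log2 values of busulfan 2 correlated as closely with Cus-1 2 (Pearson r = 0.961) as with busulfan 1 (r = 0.961), while busulfan 1 and Cus-1 1 were farthest apart (r = 0.889), genes not being independent replicates. The first principal component held 65.8% of the variance and placed busulfan 1 at -62.6, busulfan 2 at -23.8, Cus-1 2 at 19.4 and Cus-1 1 at 67.0.

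Testes treated with Cus-1 had higher levels of meiotic and postmeiotic germ cell genes and lower levels of Sertoli, Leydig, stromal and macrophage genes than testes given busulfan alone. The median log2 fold change was 0.80 for 34 spermatocyte genes, 1.07 for 30 round spermatid genes and 1.19 for 32 elongating spermatid genes, against -0.71 for 32 Sertoli cell genes. No single gene passed the adjusted threshold among the 19837 tested, and 3576 genes were higher and 1975 lower at an unadjusted limma p under 0.05, where chance gives 992. These counts were 1159 and 426 without busulfan 1 and 1438 and 616 without Cus-1 1, and their balance followed the scaling, with 2831 and 2697 under quantile normalization and 10096 and 73 after centring on Sertoli genes. Of the 26 lists, 4 were called higher and 14 lower by camera at the preset correlation. With an estimated correlation 0 were called, and the camera adjusted p was 0.489 for 17 of the 18 and 0.498 for cholesterol synthesis. With 4 libraries the latter setting can hardly call any list, so it does not decide whether the calls hold. Centring each library on the Sertoli list moved the median log2 fold change of all genes from 0.04 to 0.71, and turned 19 list medians from negative to positive, so directions are given relative to all genes.

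**Figure D1:**
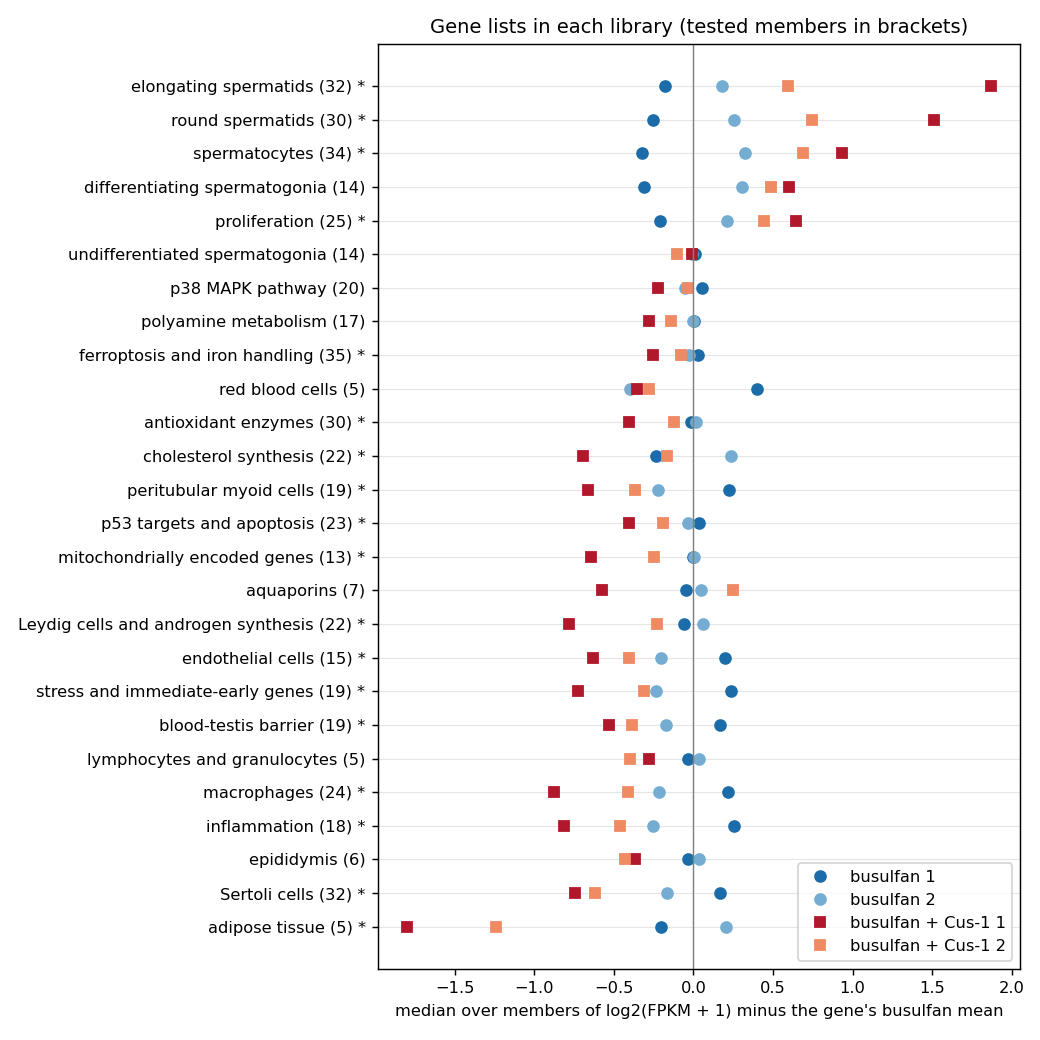
Each row is a gene list, with its number of tested members in brackets and an asterisk where camera called it at the preset correlation. Points give, for each of the 4 libraries, the median over members of log2(FPKM + 1) minus the gene's mean in the busulfan libraries, circles for busulfan and squares for busulfan with Cus-1. Elongating spermatid genes lie at 1.87 in Cus-1 1 and at 0.59 in Cus-1 2, and Sertoli cell genes at -0.75 and -0.62. No list is called with an estimated correlation.

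The spermatocyte, round spermatid and elongating spermatid lists were called higher (camera adjusted p = 1.22e-08, 4.67e-09 and 4.86e-07, and 0.489 for each with an estimated correlation). All 34 spermatocyte genes had a positive log2 fold change, and 33 were higher in both Cus-1 libraries than in both busulfan libraries (chance puts groups of 2 apart in 33.3% of genes, in either direction, and 68.4% of all tested genes were apart). Ldhc, the lactate dehydrogenase of germ cells, was at 1090 ± 262 FPKM with busulfan and 1936 ± 160 with Cus-1 (SD, n = 2), and Mael, which acts in transposon silencing, at 322 ± 77.2 and 592 ± 56.4. Of the 30 round spermatid genes, 27 were higher in both Cus-1 libraries, and 23 passed when adjusted over the list alone, against 0 when adjusted over all genes. Pgam2, a glycolytic mutase, had a log2 fold change of 0.99 (SE 0.29), and Tbpl1, a TBP-like factor needed for spermatid genes, one of 0.82 (SE 0.21). Of the 32 elongating spermatid genes 31 were higher in both, among them Tnp1 and Prm1, which replace histones in sperm chromatin. Tnp1 was at 886 and 793 FPKM with busulfan and at 3062 and 1155 with Cus-1, and Prm1 at 820 and 862 against 2926 and 1004. Adjusted over the list alone, 0 spermatocyte and 0 elongating spermatid genes passed. The elongating spermatid median was 0.59 without Cus-1 1 and 1.87 without Cus-1 2, and the spermatocyte median was 0.47 without busulfan 1, all 3 lists being called each time at the preset correlation and none with an estimated one over all 4 libraries (adjusted p = 0.489).

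Neither list of spermatogonia was called. The 14 tested genes of undifferentiated spermatogonia, the pool that holds the stem cells, had a median of -0.08 (camera adjusted p = 0.383), with Tspan8 at -0.54 (SE 0.21) and Etv5, a factor of stem cell renewal, at -0.36 (SE 0.22). The median of this list was 0.01 without busulfan 1 and -0.01 without Cus-1 2. The median log2 value of its members was only 1.76 in busulfan 1 and 1.95 in Cus-1 2, where the scale understates changes. A small median therefore does not show that these cells were unchanged. The 14 genes of differentiating spermatogonia had a median of 0.56 (adjusted p = 0.164), which ran from 0.20 without busulfan 1 to 0.96 without busulfan 2, the latter with a call. Dmrtb1, a regulator of the entry into meiosis, was at 176 ± 63.2 FPKM with busulfan and 295 ± 12.7 with Cus-1, and Tex101 had a log2 fold change of 0.90 (SE 0.37), with 0.37 without busulfan 1 and 1.43 without busulfan 2. Tspan8 was at -0.35 without Cus-1 1, and Etv5 at -0.13 without busulfan 1, -0.60 without busulfan 2 and -0.23 without Cus-1 1. In neither list did a gene pass when adjusted over the list alone. Proliferation genes were called higher (25 genes, median 0.54, camera adjusted p = 0.000171, 0.489 with an estimated correlation), with 20 of them higher in both Cus-1 libraries and 0 past the threshold over the list alone. Aurka, a mitotic kinase, had a log2 fold change of 0.65 (SE 0.23) and Cdk1 one of 0.28 (SE 0.13), Aurka being at 0.43 without Cus-1 1.

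Genes of the somatic cells of the testis were lower. Of 32 Sertoli cell genes, 29 were lower in both Cus-1 libraries, and 18 passed when adjusted over the list alone, against 0 over all genes. Clu was at 3243 ± 891 FPKM with busulfan and 2009 ± 320 with Cus-1, and Ptgds, a prostaglandin synthase on the Sertoli and the Leydig list, at 2713 ± 133 and 1402 ± 248. The 22 Leydig cell and androgen synthesis genes had a median of -0.47, with 16 lower in both libraries. Insl3, a Leydig cell hormone, was the source of 3.16% and 2.76% of the summed FPKM with busulfan and of 1.41% and 1.98% with Cus-1 (log2 fold change -0.82, SE 0.45). Peritubular myoid genes had a median of -0.42 over 19 genes, with Dcn at -0.71 (SE 0.31) and Myl9 at -0.34 (SE 0.32). Dcn was at -0.31 without busulfan 1 and -1.10 without busulfan 2, and Myl9 at -0.03, -0.64, -0.01 and -0.67 without busulfan 1, busulfan 2, Cus-1 1 and Cus-1 2. Endothelial genes had one of -0.48 over 15, with Cldn5 at -0.66 (SE 0.25, -0.43 without busulfan 1) and Egfl7 at -0.38 (SE 0.18). Blood-testis barrier genes had a median of -0.51 over 19, with Cldn11, the tight junction claudin of Sertoli cells, at -0.75 (SE 0.21) and Ctnnb1 at -0.38 (SE 0.16). In the Leydig, peritubular, endothelial and barrier lists 0 genes passed over the list alone. The camera adjusted p was 2.58e-10 for Sertoli, 4.68e-05 for Leydig, 0.000612 for peritubular, 0.000636 for endothelial and 0.000357 for barrier genes, and 0.489 for each with an estimated correlation. The Leydig median ran from -0.78 without Cus-1 2 to -0.23 without Cus-1 1 and the peritubular median from -0.70 without busulfan 2 and -0.66 without Cus-1 2 to -0.25 without busulfan 1.

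The macrophage and inflammation lists were called lower. The 24 macrophage genes had a median of -0.63 (camera adjusted p = 9.74e-08, 0.489 with an estimated correlation), 18 of them lower in both Cus-1 libraries and 7 past the threshold over the list alone. The most abundant were Apoe, at 1664 ± 224 FPKM with busulfan and 1193 ± 212 with Cus-1, and the lysozyme gene Lyz2, at 312 ± 28.5 and 206 ± 70.1. Cd74, the invariant chain of antigen presentation, chosen after its values were seen, had the smallest p of the list and was at 75.7 ± 17.8 and 17.8 ± 0.757 FPKM (log2 fold change -2.01, SE 0.21). The 18 inflammation genes had a median of -0.66 (adjusted p = 4.45e-05, 0.489 with an estimated correlation). Vcam1, an adhesion molecule for leukocytes, was at 603 ± 101 FPKM with busulfan and 325.5 ± 33.0 with Cus-1, and the chemokine gene Cxcl12 at 83.0 ± 6.61 and 52.8 ± 17.5. The chemokine gene Ccl8, chosen after its values were seen, was the 1 member past the threshold over the list alone, at 56.4 ± 2.76 and 16.7 ± 4.21 FPKM. The 5 tested lymphocyte and granulocyte genes had a median of -0.53 (adjusted p = 0.130), Cd3d overlapping between the groups at 8.30 ± 8.67 FPKM with busulfan and 16.3 ± 3.51 with Cus-1 (log2 fold change 1.29, SE 0.76) and Ighm, the heavy chain of IgM, passing over the list alone at 12.1 ± 2.70 against 3.03 ± 0.566 FPKM. The macrophage median was -0.41 without Cus-1 1 and the inflammation median -0.42 without busulfan 1. Cd3d was at 0.15 without busulfan 1 and 2.43 without busulfan 2. The lymphocyte and granulocyte list was called lower with no low-value filter (median -0.07, adjusted p = 0.0276) and without Cus-1 1 (median -0.40), and its median was -0.34 without busulfan 1 and -0.28 without Cus-1 2.

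The genes of the series title went in several directions and none passed the adjusted threshold. Sat1, the spermidine and spermine acetyltransferase on chromosome X (155213132 to 155216449), was at 61.2 and 41.0 FPKM with busulfan and at 22.9 and 34.0 with Cus-1 (log2 fold change -0.82, SE 0.29, limma adjusted p = 0.165), with -0.54 without busulfan 1 and -0.55 without Cus-1 1. Gpx4, the peroxidase that reduces lipid peroxides, on chromosome 10 (80047166 to 80056439), was at 548 and 638 FPKM with busulfan and at 893 and 751 with Cus-1 (0.47, SE 0.20, adjusted p = 0.196). Mapk14, which encodes p38 alpha, on chromosome 17 (28691329 to 28748406), was at 22.0 and 20.1 against 17.2 and 17.5 FPKM (-0.26, SE 0.16, adjusted p = 0.290). For all 3 genes both Cus-1 libraries lay beyond both busulfan libraries. Of the 12 aquaporin genes 7 were tested, with a median of -0.45 (camera adjusted p = 0.623). This median turned to 0.25 without Cus-1 1 and to 0.05 with a 5 FPKM filter. Without busulfan 2 and with no low-value filter it was 0.01, still below the median of all genes there (0.06 and 0.03). Adjusted over the list alone, the water and glycerol channel gene Aqp7 and Aqp11 were higher, with log2 fold changes of 1.33 (SE 0.25) and 0.92 (SE 0.29), and Aqp5 and Aqp8 were lower, with -1.43 (SE 0.27) and -0.87 (SE 0.19). Aqp9 was at 25.7 ± 5.71 FPKM with busulfan and 37.9 ± 2.84 with Cus-1, Aqp1 at 1.37 ± 0.474 and 0.535 ± 0.0495, and Aqp2 overlapped between the groups.

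**Figure D2:**
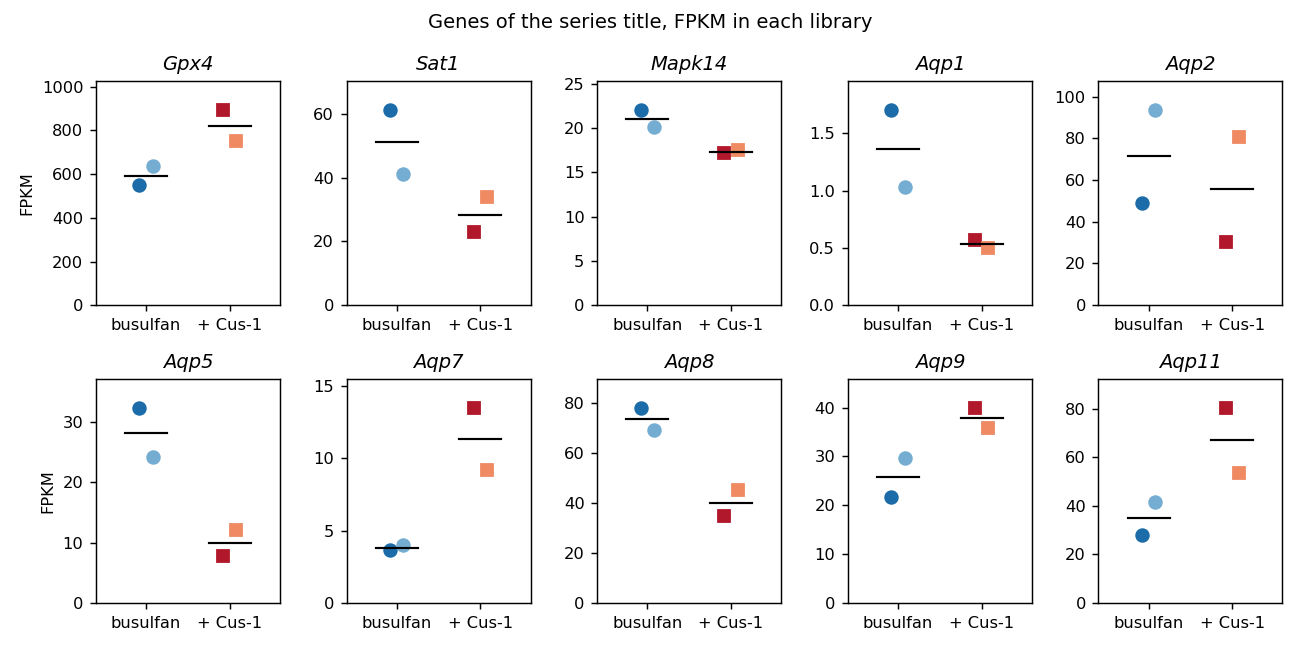
FPKM of the genes named in the series title and of each tested aquaporin, 1 panel per gene with its own axis from 0. Points are the 4 libraries, circles for busulfan and squares for busulfan with Cus-1, and bars mark the mean of the 2 libraries. Gpx4 lies at 548 and 638 FPKM with busulfan and at 893 and 751 with Cus-1, while Aqp2 overlaps between the groups.

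The pathway lists around these genes held members that went both ways. Of the ferroptosis genes 9 were higher and 15 lower in both Cus-1 libraries, and of the polyamine genes 5 and 11, where chance puts 33.3% apart and 68.4% of all tested genes were. The 35 ferroptosis and iron handling genes had a median of -0.22 (camera adjusted p = 0.0357, 0.489 with an estimated correlation), and 0 passed over the list alone. This list pools genes that favour ferroptosis with genes that guard against it, so its median does not tell whether ferroptosis was lower. Whether a shift in cell mixture alone gave that median was not tested. The ferritin genes Fth1 and Ftl1, which store iron, had log2 fold changes of -0.47 (SE 0.26) and -0.73 (SE 0.29). Without Cus-1 1 they were at -0.20 and -0.37, and Fth1 was at -0.74 without Cus-1 2. The list's call was lost without busulfan 1 and without Cus-1 1, with a median of -0.08 in each case, and with no low-value filter the median was -0.09. The 20 p38 MAPK pathway genes had a median of -0.16 (adjusted p = 0.0795), with Hspb1 at -0.76 (SE 0.26, -0.48 without busulfan 1) and Ddit3 at 0.12 (SE 0.15), the latter at 0.05, 0.19, 0.06 and 0.18 without busulfan 1, busulfan 2, Cus-1 1 and Cus-1 2. The 17 polyamine metabolism genes had a median of -0.17 (adjusted p = 0.0944), with Slc3a2 at -0.48 (SE 0.23) and the antizyme gene Oaz1 at -0.17 (SE 0.15). Slc3a2 was at -0.22 without Cus-1 1 and -0.74 without Cus-1 2, and Oaz1 at -0.08 without busulfan 1 and -0.25 without busulfan 2. Chosen after their values were seen, Odc1, which makes putrescine, was at 0.53 (SE 0.17) and Srm, the spermidine synthase, at -0.66 (SE 0.21). The p38 median was -0.04 without Cus-1 1 and the polyamine median -0.28 without Cus-1 2, and in both lists 0 genes passed over the list alone. With no low-value filter both were called lower at the preset correlation, p38 at -0.09 (adjusted p = 0.0318) and polyamines at -0.17 (0.0383). The 30 antioxidant enzyme genes had a median of -0.33 (adjusted p = 0.0306, 0.489 with an estimated correlation), 0 of them past the threshold over the list alone, and Gstm1 was at 2978 ± 117 FPKM with busulfan and 2065 ± 443 with Cus-1. That call was lost without busulfan 2 and without Cus-1 1, where the median was -0.32 and -0.12.

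Lists of p53 targets, stress genes, cholesterol synthesis and mitochondrially encoded genes were called lower. Their medians lay near those of the somatic cell lists, which ran from -0.71 for Sertoli to -0.42 for peritubular genes. Whether a shift in cell mixture alone gave them was not tested. The 23 p53 target and apoptosis genes had a median of -0.43 (camera adjusted p = 0.00117, 0.489 with an estimated correlation), although its most abundant members were higher, Mdm2 at 0.43 (SE 0.15) and the survival gene Bcl2l1 at 0.22 (SE 0.15, 0.13 without Cus-1 1). The 19 stress and immediate-early genes had a median of -0.51 (adjusted p = 0.00475, 0.489 with an estimated correlation), with the heat shock gene Dnajb1 at 0.63 (SE 0.18) and Jund at -0.37 (SE 0.23, -0.10 without busulfan 1 and -0.64 without busulfan 2), and 10 of the 19 overlapped between the groups. The 22 cholesterol synthesis genes had a median of -0.41 (adjusted p = 0.000698, 0.498 with an estimated correlation), with Fdps at -0.43 (SE 0.28) and Hmgcs1 at -0.66 (SE 0.25). Fdps was at -0.67, -0.19, -0.13 and -0.73 without busulfan 1, busulfan 2, Cus-1 1 and Cus-1 2, and Hmgcs1 at -0.99 without busulfan 1 and -0.32 without busulfan 2. In these 3 lists 0 genes passed over the list alone. The 13 mitochondrially encoded genes had a median of -0.45 (adjusted p = 0.00240, 0.489 with an estimated correlation) and made up 8.50% and 8.57% of the summed FPKM with busulfan and 5.84% and 7.51% with Cus-1. Only mt-Co2, whose values are uncertain, passed over that list alone, and the list was not tested without that gene. mt-Atp8 (-0.25, SE 0.49) and mt-Co1 (-0.45, SE 0.40) were its most abundant members, mt-Atp8 being at -0.15 without busulfan 2, -0.06 without Cus-1 1 and -0.43 without Cus-1 2, and mt-Co1 at -0.25 without Cus-1 1. The stress call was lost without busulfan 1 (median -0.28) and the cholesterol call without busulfan 2 (-0.25). The stress median was also -0.78 without busulfan 2 and -0.31 without Cus-1 1, and the cholesterol median -0.17 without Cus-1 1 and -0.69 without Cus-1 2. The p53 median was -0.19 and the mitochondrial median -0.25 without Cus-1 1.

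Markers of tissues around the testis were also measured. The 5 tested of 11 adipose tissue genes had a median of -1.54 (camera adjusted p = 0.00197, 0.489 with an estimated correlation), and 3 passed over the list alone, Cfd, Fabp4 and Car3, named after their values were seen. Fabp4, a fatty acid carrier of fat cells, was at 7.49 ± 0.276 FPKM with busulfan and 1.96 ± 0.728 with Cus-1, while the most abundant members, Cidea and Plin1, overlapped between the groups. With no low-value filter the adipose median was -0.33, still called. The 5 tested red blood cell genes had a median of -0.28 (adjusted p = 0.139), with Hba-a2 at 261 ± 122 and 153 ± 8.60 FPKM and Hbb-bs at 144 ± 55.1 and 91.7 ± 13.2. Their median was 0.01 without busulfan 1 and -0.89, with a call, without busulfan 2. The 6 tested of 22 epididymis genes had a median of -0.66 (adjusted p = 0.233), with Lcn2 at 3760 ± 538 and 2337 ± 813 FPKM and Wfdc10 at 410.1 ± 68.0 and 269.9 ± 25.96. The epididymis median was -0.33 without busulfan 1, -0.43 without Cus-1 1 and -0.37 without Cus-1 2, and 0.03 with no low-value filter. In the red blood cell and epididymis lists 0 genes passed over the list alone.

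The genes with the smallest p were mostly rows of predicted genes and pseudogenes, which can share fragments with near-identical copies, so their values are uncertain. Of the 20 named by p, 14 have Gm symbols, 8 are annotated as pseudogenes and 5 as protein coding, and 4 are not in the annotation. The smallest adjusted p was 0.0676, for Tpm3-rs7 on chromosome 14 (113314608 to 113316754), a gene related to tropomyosin 3, at 45.0 and 36.1 FPKM with busulfan and 0.14 and 0.33 with Cus-1. Ahcy, which hydrolyses S-adenosylhomocysteine, on chromosome 2 (155059310 to 155074497), was at 12.9 and 10.6 against 0.46 and 0.47 FPKM, and its neighbour Gm14226 (155018266 to 155027104) at 117 and 116 against 40.8 and 34.9. The mitochondrial gene mt-Co2, a subunit of cytochrome oxidase that every respiring cell uses, was at 38.7 and 88.9 FPKM with busulfan and listed at 0 in both Cus-1 libraries. As mt-Co1 was at 9308 FPKM or more in all 4 libraries, the values of mt-Co2 may be failed estimates in both groups. Also listed at 0 in both Cus-1 libraries were Gm6314, Mpc1-ps and Gm10240, and in both busulfan libraries Gm43110, Gm5611 and Gm45893. Gm43110 was at 22.8 and 39.7 FPKM with Cus-1, Gm5611 at 7.75 and 19, and Gm45893 at 2.84 and 3.30. The remaining named genes that were higher were Gm69616, Gm9118, Gm13165, 4930533I22Rik, Gm6653, Gm32102 and Gm60288, and those that were lower were BC021767, Gm72022 and Gm8113. Without Cus-1 1, 2 genes passed the threshold as higher and 5 as lower.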

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

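How the results depend on the processing was measured with alternative filters, scalings, models and sets of libraries, 1 of them added later, and the comparison rests on 2 libraries against 2, where a lone left-out partner is assumed to vary like the other group. No paired analysis was possible because the sample titles give the 2 groups different numbers, so no number is shared. Turns are counted here by the raw sign, not relative to all genes. Of the list medians, 350 kept direction and call, 29 lost a call, 6 gained one and 26 turned. Of those 26, 2 also lost a call and 3 gained one, and 19 were turned by the Sertoli centring. Of the gene values, 1084 kept direction, 40 passed the threshold only in the alternative and 28 turned. The cause was not tested, except for the Sertoli centring, which adds about the same shift of 0.665 to every gene by construction, so a sign that turns there is arithmetic and bears on no direction relative to all genes. With all 4 libraries 0 genes were higher and 0 lower. Centring on the Sertoli list gave 5930 and 42, and an unadjusted p with a 2-fold change 1176 and 253. Keeping only protein-coding genes gave 0 and 3, the 3 being Tpm3-rs7, Ahcy and mt-Co2, which were near 0 or listed at 0 in both Cus-1 libraries. Single genes called without Cus-1 1 are not counted, as they rest on a lone Cus-1 sample. The smallest adjusted p ran from 0.00823 with protein-coding genes only to 0.320 with no low-value filter. The counts at an unadjusted p under 0.05, 3576 and 1975, were 2943 and 2731 with the total taken without mitochondrial and the 100 most abundant genes. The 18 list calls went to 0 with an estimated correlation, a setting that can hardly call any list with 4 libraries.

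Under Sertoli centring these list medians turned positive, 13 of the 19 being called lower than other genes by camera and 6 not (p38, ferroptosis, polyamines, undifferentiated spermatogonia, red blood cells and antioxidant, adjusted p from 0.0935 to 0.562): aquaporins 0.22, p38 0.50, ferroptosis 0.45, polyamines 0.49, undifferentiated spermatogonia 0.58, Leydig 0.19, peritubular 0.25, macrophages 0.0345, lymphocytes 0.13, endothelial 0.19, red blood cells 0.39, epididymis 0.00577, inflammation 0.00622, antioxidant 0.34, barrier 0.15, p53 0.23, cholesterol 0.26, stress 0.15 and mitochondrial 0.22. The ferroptosis and antioxidant calls were thus lost there (adjusted p = 0.111 for both), and aquaporins (0.0369), epididymis (0.0218) and lymphocytes (0.00355) gained one. These genes turned positive too: Aqp1 0.0556, Aqp2 0.22, Mapk14 0.40, Fth1 0.19, Slc3a2 0.19, Oaz1 0.50, Tspan8 0.13, Etv5 0.30, Myl9 0.33, Apoe 0.18, Lyz2 0.0291, Cldn5 0.00342, Egfl7 0.29, Hbb-bs 0.0652, Wfdc10 0.0700, Cidea 0.33, Plin1 0.21, Gstm1 0.12, Ctnnb1 0.29, Fdps 0.24, Hmgcs1 0.00771, Jund 0.30, mt-Atp8 0.42 and mt-Co1 0.22. Quantile normalization put Ddit3 at -0.000760, which is 0.06 relative to all genes. Relative to all genes it also put Insl3 and mt-Atp8 at 0.06, mt-Co1 at 0.04 and the mitochondrial list at -0.24 (from -0.87, -0.29, -0.49 and -0.49), and as it gives equal ranks equal values, the most abundant genes can show little change there. It put Clu at -0.28, Ptgds at -0.59, Gstm1 at -0.18 and Cdk1 at 0.14. With no low-value filter aquaporins were at 0.0130 and epididymis at 0.0283, neither above the median of all genes there (0.0283). In that setting p38, polyamines and lymphocytes gained a call. With a 5 FPKM filter aquaporins were at 0.0550, above all genes (-0.00556), and undifferentiated spermatogonia at -0.36. Without busulfan 1, undifferentiated spermatogonia were at 0.00828 and red blood cells at 0.0122, both still below all genes (0.0254). Without busulfan 2, the aquaporin list and its middle gene Aqp2 were both at 0.00864, still below all genes (0.0597), and Plin1 was above them at 0.18. Without Cus-1 1, the aquaporin list and Aqp2 were both at 0.25, above all genes (0.0314). The ferroptosis call was also lost with a 5 FPKM filter (-0.19) and with protein-coding genes only, the antioxidant call in the same 2 alternatives (-0.31 with the filter), and the stress call with the filter (-0.51).

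Leaving out each library in turn gave medians from 0.47 to 1.14 for spermatocytes, 0.74 to 1.51 for round spermatids, 0.59 to 1.87 for elongating spermatids, 0.37 to 0.79 for proliferation, -0.85 to -0.53 for Sertoli, -0.87 to -0.41 for macrophage, -0.63 to -0.33 for endothelial, -0.91 to -0.42 for inflammation, -1.80 to -1.24 for adipose, -0.58 to 0.25 for aquaporin, -0.11 to 0.00828 for undifferentiated spermatogonia, -0.89 to 0.0122 for red blood cell and -0.66 to -0.36 for barrier genes, and log2 fold changes from -1.14 to 0.25 for Aqp2 and -1.10 to 0.18 for Plin1. Genes given above by their FPKM alone also moved by more than 1.5 times, with log2 fold changes from -0.82 to -0.40 for Aqp1, 0.34 to 0.78 for Aqp9, 0.42 to 1.16 for Dmrtb1, 0.46 to 1.87 for Tnp1, 0.26 to 1.80 for Prm1, -0.96 to -0.39 for Clu, -0.67 to -0.30 for Apoe, -0.99 to -0.28 for Lyz2, 0.15 to 2.43 for Cd3d, -1.18 to -0.19 for Hba-a2, -0.997 to -0.20 for Hbb-bs, -1.09 to -0.36 for Lcn2, -0.55 to -0.12 for Cidea, -1.02 to -0.34 for Cxcl12 and -0.77 to -0.32 for Gstm1. Of the 18 called lists, 14 stayed called without each library.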

Other observations

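The sets in this paragraph were chosen after the values were seen, 32 in all, and none is called with an estimated correlation. The 1047 tested lincRNA genes had a median log2 fold change of 0.57, with 563 higher in both Cus-1 libraries and 120 lower (limma camera adjusted p = 1.1e-06, 0.688 with an estimated correlation). Processed transcripts (288 genes, 0.13, adjusted p = 0.424) and sense intronic genes (38 genes, 0.09, adjusted p = 0.835) were not called. The 734 antisense genes, whose values are uncertain because the strand setting is not given in the sources used here, had one of 0.48, and 851 Rik genes of the series named from testis libraries one of 0.81. The 651 genes of chromosome X, which is silenced in meiosis, had a median of -0.39, with 371 lower and 113 higher in both (adjusted p = 1.1e-06, 0.688 with an estimated correlation). Sat1 lies on that chromosome.

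The class II genes were also chosen after their values were seen, and their test was changed after a first outcome. H2-Aa, an antigen-presenting chain, was at 43.6 ± 15.7 FPKM with busulfan and 11.4 ± 0.262 with Cus-1 (SD, n = 2), and H2-Eb1 at 14.1 ± 2.86 and 4.13 ± 0.361. The first test took the 4 class II genes on the macrophage list (median -1.67) against its 20 other members (-0.58) and gave an exact permutation p of 0.000941, which decides nothing because those 4 had been picked for the pattern. It was replaced by 3 class II genes outside the list, H2-DMa (-0.12), H2-DMb2 (-0.64) and H2-DMb1 (-1.33). Their median was -0.64 and their exact permutation p 0.6951, so they did not differ from the other members by more than regroupings give. With Cus-1, H2-DMb2 was at a mean of 1.08 FPKM and H2-DMb1 at 1.45, where the scale understates changes. With only 3 genes the test cannot decide whether class II genes fell further than other members.

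For the patterns below, only the tests of 1 library and of FPKM scaling were written before their outcomes were seen. The bounds for dilution, for a strain difference and for Gpx4 were changed after their values were known, each time to one that leaves the explanation open.

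Germ cell lists were higher and somatic lists lower, and a larger share of germ cells could dilute every somatic type alike. The 5 somatic medians differed more than regrouped members did (permutation p = 0.0341 over genes, not animals). The gap to Sertoli genes moved by more than 2 SDs in 1 of 4 lists, endothelial (0.178, SD 0.031). It did not in Leydig (0.199, SD 0.288), peritubular (0.161, SD 0.112) or macrophage genes (0.030, SD 0.138). The log2 scale with its pseudocount understates changes at low values. Endothelial genes had a median log2 value of 2.92 and 2.47 in busulfan 1 and 2, against 5.93 and 5.72 for Sertoli genes. Equal dilution could thus give part of the endothelial gap and of the range of medians, so dilution stays open. Without each library in turn the medians kept their sign. They were 0.47 to 1.14 for spermatocyte, 0.74 to 1.51 for round spermatid, 0.59 to 1.87 for elongating spermatid and -0.85 to -0.53 for Sertoli genes. These values argue against 1 library carrying the whole difference in these 4 lists. How much of its size rests on 1 library stays open. The lowest share of a median kept without 1 library was 0.4964, just under the bound of 0.5 set before. Scaling by 1 factor per library shifts genes far above the pseudocount about alike, so it is no source of the gap between germ and Sertoli genes (spermatocytes 0.77 and Sertoli -0.76 relative to all genes with a common total, 0.76 and -0.75 without), though the thinly filled adipose list went from -1.58 to -1.12, and which side moved stays open, as median-of-ratios scaling (lowest share kept 0.9481) moved the median of all genes only from 0.04 to 0.0015. Counts of cells in sections of these testes would decide.

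Rows near 0 in one group led the gene ranking, which shared fragments between near-identical copies could produce without any effect of Cus-1. The real split had 12 such rows and the other 2 splits of the 4 libraries 13 and 7, so such rows also arise between libraries of both groups. A strain difference stays open, because of these rows 7, 3 and 4 were pseudogenes and 3, 1 and 0 protein coding, with more of both in the real split, and Ahcy and Gm14226 lie 32206 bases apart. At an unadjusted limma p under 0.05 the real split gave 5551 genes and the others 207 and 311, but 3 splits are too few for a share under 0.05. Gm10240 and Gm13370 in the real split had the same values, 6.78 and 12.19 FPKM with busulfan and 0 and 0 with Cus-1. In another split Gm43520 and Gm43535 did, at 16.8 and 0 with busulfan and 23.12 and 0 with Cus-1. Fragments shared between copies would give such pairs, so the counts of rows are not all of separate genes. Reads placed on the copies would decide.

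Sat1 was lower and Gpx4 higher, and a shift in cell mixture alone could give both. Sat1 lay at percentile 20.72 of the somatic list members, inside bounds of 5 and 95 written after its value was seen. Such a shift would put it there, but other causes could too, so this test does not decide. Gpx4 lay at percentile 3.226 of the spermatid members, below the first bound of 5, which would have spoken against mixture alone. The bound was rewritten because somatic cells make Gpx4 too, and with the new one the test does not decide. Gpx4 and Sat1 measured in sorted cells would separate mixture from regulation.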
